A study of Arabidopsis thaliana with 12 samples.

How the data were processed

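The data were 12 arrays of total RNA from whole *Arabidopsis thaliana* seedlings, per the labels. The Columbia wild type (WT) and *arf2-6*, a mutant of the auxin response factor gene *ARF2*, were grown for 7 days in shaken liquid medium with 1.5% sucrose under 16 h of light and 8 h of dark. The seedlings then received 5 µM indole-3-acetic acid (IAA), the main natural auxin, or the solvent ethanol as control for 2 h at 24 °C. The 4 groups (WT_control, WT_IAA, arf2-6_control and arf2-6_IAA) held 3 arrays each. The groups and replicate numbers came from the labels. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

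The values were log2 signals deposited by the authors, 1 per probe set and array, for 22810 probe sets, of which 64 were AFFX controls. How the signals were summarised and scaled before deposition is not given in the sources used here. The values reached no lower than 5.64 log2 (a signal of 50) on any array, and 42.5 to 43.2% of the probe sets lay at that lowest value on an array. On all 12 arrays together 8531 probe sets (37.5%) lay there. A difference against a group at the lowest value on all 3 arrays is a lower bound and is written as at least N-fold, and such differences were ranked at their fitted size. The same wording is used where 2 of the 3 arrays are said to lie there. Averaged differences and interactions that use such a group are fitted values, not exact sizes. A probe set at the lowest value throughout a group also shows no spread there, which lowers the error estimated for it. The array medians lay between 6.16 and 6.22 log2 and the upper quartiles between 7.72 and 7.80, so the deposited scaling was kept. The number of arrays limits the precision.

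Gene names were taken from the platform annotation given for the probe sets and updated through a gene table of assembly TAIR10.1, which was used only for names and for the order of neighbouring genes. A single gene was paired with 13513 probe sets, several genes with 503, and 8794 were not listed with a gene and are reported by probe set identifier where they appear. Of the single-gene probe sets, 13436 matched the gene table and 11933 carried only a locus code as symbol. The transcript of *ARF2* itself (AT5G62000) was paired with 0 probe sets and could not be identified here. No gene was named from a probe set with several genes.

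Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with tables and plots made in Python 3.11.15. One model with a mean per group was fitted over the 12 arrays, with 8 residual degrees of freedom, a variance prior that follows mean signal, two-sided tests and Benjamini-Hochberg adjustment, and a call required an adjusted p under 0.05. The AFFX controls and the 30% of probe sets with the lowest mean over all arrays were left out. This removed the 8531 at the lowest value everywhere and left 14215. The contrasts were the IAA effect in each genotype, the genotype effect in control and in IAA-treated seedlings and averaged over both, and the IAA by genotype interaction (the IAA effect in *arf2-6* minus that in the wild type). Log2 differences are given with their standard error (SE), and group levels as mean ± SD with n = 3.

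The groups, tests, filter, lists and the rule for named genes were fixed before the data were examined. The 22 lists held 401 genes from textbook knowledge, on auxin, other hormones, growth, stress and markers of leaf, root and root hair. Of these, 57 had a single-gene probe set. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Counts of called members are given over all genes and adjusted over the list alone. The rule named, for each contrast, the 10 largest rises and the 10 largest falls among single-gene probe sets that were called and showed no overlap between the replicate values of the groups compared, which chance gives for 10% of genes with 3 arrays against 3. The interaction had 5 each way without that condition. It also named *ARF2*, up to 4 called members of each list with the lowest p, or 1 member as a value where none was called, and the value in *arf2-6* of any gene named for IAA in the wild type. In the simple contrasts, every gene named as called had all 3 arrays of one group beyond all 3 of the other.

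A further 24 gene families, taken from symbols of the gene table, were written after the table was opened and before any of their differences was seen, and were tested with at least 5 members. A list of class III peroxidases and a list of all chloroplast-encoded genes were written only after the named genes had been seen, and were also tested without the members seen first. On simulated data with 200 changed probe sets among 14215, the fit recovered 2-fold changes in 82.1% of cases for IAA in the wild type, 68.7% for IAA in *arf2-6*, 82.1% for genotype in controls, 74.6% for genotype with IAA, 92.5% for the averaged genotype effect and 59.7% for the interaction. In the same order, changes of 0.5 log2 were recovered in 31.3, 34.3, 23.9, 25.4, 58.2 and 13.4% of cases. False calls were 10 of 149, 7 of 134, 6 of 134, 4 of 132, 12 of 171 and 9 of 115. Camera called 20 of 20 shifted lists of 10 genes and 1 unshifted list. Both simulations drew noise independently for each probe set and array. They held no deviations shared between arrays or genes, so these rates need not hold for the real data. Of the AFFX probe sets, 35 lay above the lowest value and 0 were called in any contrast.

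Alternatives were quantile normalization, centring on the upper quartile, no filter, a filter of 50%, no variance trend, array weights, a 2-fold minimum, only the groups of the contrast, the replicate number as a block, and leaving out each array in turn. The 3 choices added after seeing the data were a filter on probe sets above the lowest value throughout a group, leaving out the 2 control arrays WT_control 3 and arf2-6_control 2, and a fixed term shared by them. Pseudocounts apply to linear values and were not run.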

Results

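Transcript levels were measured on 12 one-colour Affymetrix arrays from seedlings of wild-type *Arabidopsis* and of the *arf2-6* mutant, each given IAA or the solvent alone for 2 h. The 4 groups held 3 arrays each. Between 12914 and 13075 probe sets lay above the lowest deposited value on an array, and array medians ranged from 6.16 to 6.22 log2. The first principal component of the tested probe sets (40.5% of the variance) parted IAA from control arrays, at 15.9 to 23.4 against -31.1 to -13.0. The second (24.6%) parted the genotypes, at 3.80 to 20.1 in *arf2-6* and -27.1 to -8.21 in the wild type. The design asked how auxin changes transcript levels in each genotype, how the genotypes differ with and without auxin, and whether the auxin response itself differs.

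No probe set was listed with the mutated gene, so its transcript could not be identified here and did not check the labels. The probe set with the largest averaged genotype difference in either direction, 247468_at, which is not listed with a gene and was picked after its values were seen, lay at the lowest value on all 6 *arf2-6* arrays. It measured 8.06 ± 0.34 log2 in WT_control and 8.61 ± 0.20 in WT_IAA (SD, n = 3). The averaged difference was -2.69 log2 (SE 0.11, adjusted p = 8.2e-07), at least 6.47-fold lower in *arf2-6*. Which gene this probe set measures, and whether that is *ARF2*, cannot be told from the annotation given.

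Among the named genes above the lowest value in WT_control, *GH3.3* and *WES1* rose most with IAA in wild-type seedlings. *GH3.3*, an amido synthetase that conjugates auxin to amino acids, rose from 6.90 ± 0.56 to 12.7 ± 0.30 log2 (SD, n = 3), a 55.0-fold change (log2 5.78, SE 0.32, adjusted p = 7.0e-07). Its relatives *WES1* (also called *GH3.5*) and *GH3.1* rose 19.7-fold and at least 6.55-fold, while *GH3.17* measured 0.03 log2. Of the 4 tested GH3 genes, 3 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 3.8e-08). *IAA29* and *IAA30*, which encode Aux/IAA repressors of auxin-responsive transcription, rose at least 12.5-fold and at least 1.81-fold. They were 2 of 4 tested Aux/IAA genes over all genes and 2 of the 3 that rose adjusted over the list alone (camera adjusted p = 3.3e-05), the third being *IAA18* (log2 0.48, adjusted p = 0.090 over all genes).

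Members of the list of lateral root and patterning regulators rose as well. *LBD29* and *LBD16*, LOB-domain factors needed for lateral root initiation, rose at least 11.1-fold (log2 3.47, SE 0.16, adjusted p = 1.5e-07) and 4.04-fold (log2 2.01, SE 0.11). *HAT2*, a homeodomain-leucine zipper gene, rose 7.97-fold from 7.95 ± 0.21 log2, and *PUCHI*, an AP2/ERF factor of the lateral root primordium, rose at least 2.02-fold. These 4 of 5 tested members rose over all genes and adjusted over the list alone (camera adjusted p = 2.6e-11), and *SHI* measured 0.04 log2. Among 8 tested expansins and xyloglucan endotransglucosylases, which loosen and remodel the wall, *EXPA4* (2.95-fold), *XTH19* (2.43-fold), *XTH18* (2.34-fold) and *XTH33* (log2 0.74) rose over all genes. Adjusted over the list alone, 5 rose and 1, *XTH16* (log2 -0.79), fell (camera adjusted p = 3.4e-04). *AT2G18010* (*SAUR10*), the 1 tested SAUR gene, rose at least 2.01-fold, and *WAG2*, a kinase related to PINOID that regulates auxin transport, rose at least 2.16-fold. *RTE1*, a regulator of the ethylene receptor ETR1, rose by 1.00 log2 (SE 0.11, adjusted p = 1.1e-04).

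The 10 largest rises also held *AT1G62770* (8.07-fold), of the pectin methylesterase and invertase inhibitor family, together with *AT4G17350*, *AT5G40590*, *AT2G39980* and *AT3G26760* at 6.69-fold to 8.25-fold. Among the largest falls, *AT3G01190*, a class III peroxidase, fell from 9.17 ± 0.14 to 7.25 ± 0.19 log2 (log2 -1.92, SE 0.17, adjusted p = 2.3e-05). *AT4G25250*, an invertase and pectin methylesterase inhibitor relative, was at least 4.01-fold lower, and *AT3G45700*, a nitrate transporter relative, changed by -1.88 log2. *AT3G01260* (log2 -2.01), *GSTU26*, a tau-class glutathione S-transferase (log2 -1.43), and *AT5G62360* (log2 -1.43) fell as well, and the remaining 4 of the 10 fell by 1.34 to 1.76 log2. The 3 leaf photosynthesis markers were at camera adjusted p = 0.79, with *RCA*, the activase of Rubisco, at 0.11 log2. The 4 reference genes were also at 0.79, with *AT4G34270* at 0.19 log2. The root hair expansin *EXPA7* measured 0.20 log2, the mitotic kinase gene *AUR1* -0.39, the clock gene *GI* -0.36 and the stress zinc finger gene *STZ* 1.11 (adjusted p = 0.19). The cytokinin response regulator *RR16* (0.08), the auxin synthesis gene *YUC6* (-0.23) and *WRKY53* (0.30) were also not called, each with the lowest value throughout 1 of the 2 groups, so that these are fitted values and not exact sizes.

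**Figure D1:**
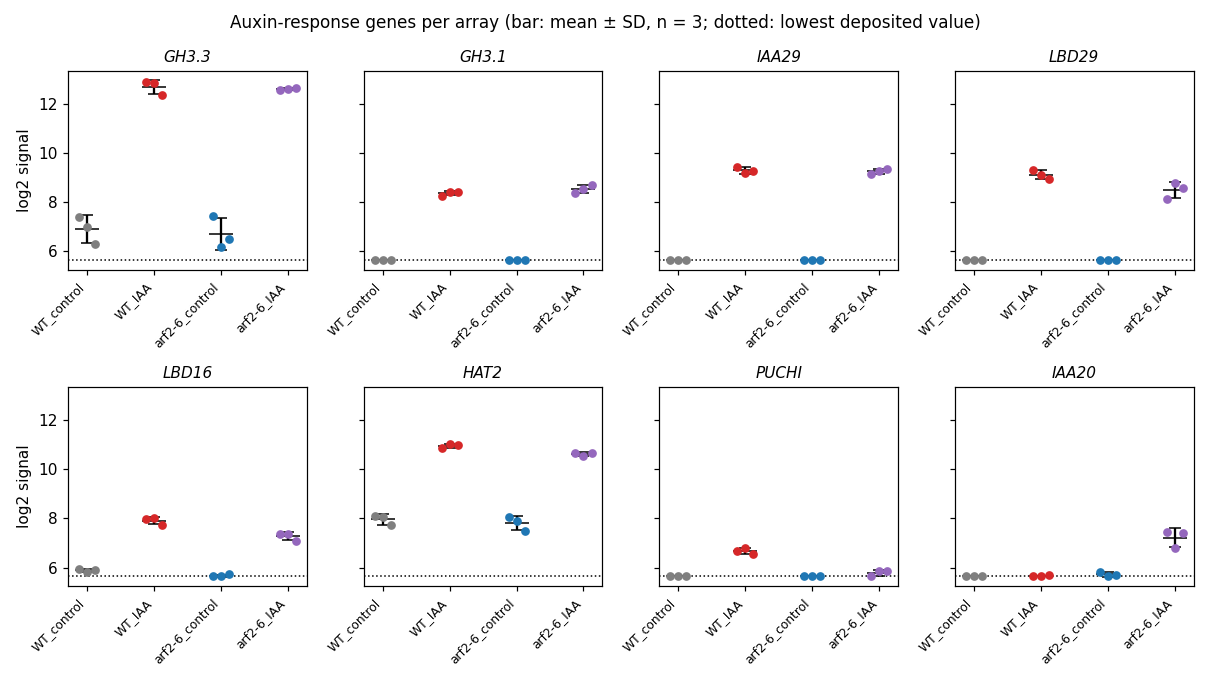
Log2 signal of 8 auxin-response genes on each of the 12 arrays, by group, with points for arrays, bars for mean ± SD (n = 3) and a dotted line at the lowest deposited value, 5.64. *GH3.3* goes from 6.90 to 12.7 in wild type, and *IAA20* averages 7.21 in arf2-6_IAA and 5.64 to 5.72 in the other groups.

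In all, 1194 of 14215 probe sets were called for IAA in the wild type, 660 higher and 534 lower, and 349 of them changed at least 2-fold. The senescence factor *WRKY6* was called at 0.47 log2 (adjusted p = 0.045), but leaving out any 1 of 11 of the 12 arrays ended that call, as did both other scalings.

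In *arf2-6*, the same gene groups rose with IAA. *GH3.3* rose 59.6-fold, from 6.70 ± 0.65 to 12.6 ± 0.03 log2 (log2 5.90, SE 0.32, adjusted p = 7.6e-07), *WES1* 24.7-fold and *GH3.1* at least 7.44-fold. *IAA29* rose at least 12.1-fold, *LBD29* at least 7.21-fold and *HAT2* 7.02-fold. *LBD16*, at the lowest value on 2 of 3 arf2-6_control arrays, rose at least 3.04-fold. *IAA20*, an Aux/IAA gene whose product lacks the degradation domain, rose from 5.72 ± 0.10 to 7.21 ± 0.37 log2 (log2 1.49, SE 0.14, adjusted p = 6.1e-05), where WT_control lay at the lowest value on all 3 arrays and WT_IAA at 5.65 ± 0.02. *PUCHI*, at the lowest value on all 3 arf2-6_control arrays, lay at 5.79 ± 0.12 in arf2-6_IAA (adjusted p = 0.33).

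Over all genes and adjusted over the list alone, 3 of 4 Aux/IAA genes rose in *arf2-6* (camera adjusted p = 6.3e-09). So did 3 of 4 GH3 genes (2.4e-09) and 3 of 5 lateral root and patterning regulators (2.4e-09). Of the expansins and XTHs, 4 of 8 rose over all genes, namely *XTH19* (2.96-fold), *EXPA4* (2.91-fold), *XTH18* (2.19-fold) and *XTH33* (at least 1.70-fold, with 2 of 3 arf2-6_control arrays at the lowest value). Adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 1.9e-04). *AT2G18010* (at least 2.19-fold), *IAA30* (at least 2.03-fold), *RTE1* (log2 0.89) and *WAG2* (at least 1.68-fold, adjusted p = 0.012) rose too. Without arf2-6_IAA 1 the adjusted p of *WAG2* was 0.052. The peroxidase gene *AT3G01190* fell from 8.94 ± 0.34 to 6.16 ± 0.15 log2 (log2 -2.78, SE 0.17, adjusted p = 2.0e-06). *AT4G39675* (log2 -2.22), the peroxidase gene *AT4G30170* (-1.72), *SFP1*, a sugar transporter gene (-1.58), and *tny*, the AP2/ERF factor TINY (-1.58), also fell. The leaf markers (camera adjusted p = 0.63) and reference genes (0.92) were not called. The 8 list calls for IAA in the 2 genotypes held with an estimated correlation, at adjusted p from 0.0012 to 0.031.

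IAA changed 1210 probe sets in *arf2-6*, 533 higher and 677 lower. The balance turned among the 337 that changed at least 2-fold, 209 higher and 128 lower, and without arf2-6_IAA 3, where the count was 769, 388 higher and 381 lower. The 2 genotypes shared 808 calls, 428 higher and 380 lower, with 0 in opposite directions. Independent lists would share 24.7 higher and 25.4 lower. The group means of the 2 effects come from different arrays. Their error was estimated from all arrays together, so the 2 lists are not independent and these expected numbers are only a rough guide. Across the 1596 probe sets called in either genotype, which are not independent replicates, the 2 log2 changes had r = 0.943, and 96.8% of the wild-type calls had the same sign in *arf2-6*.

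**Figure D2:**
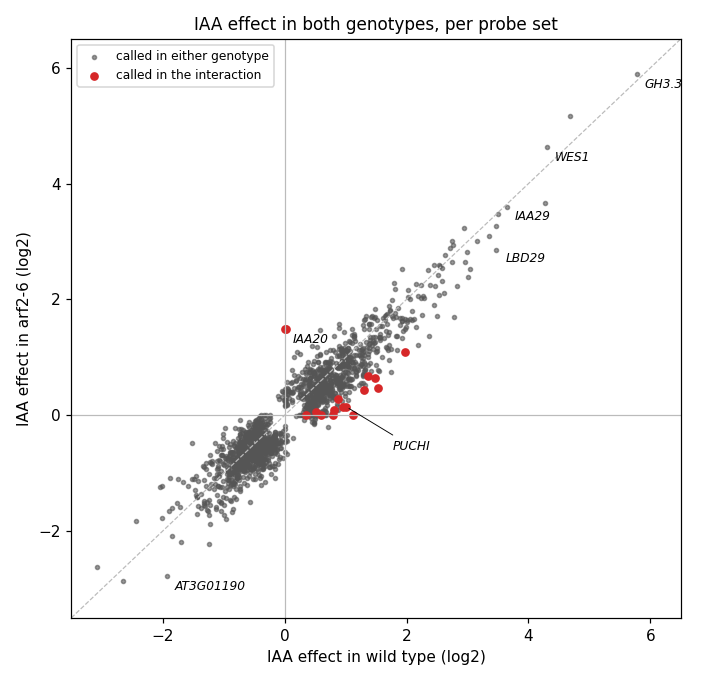
Log2 IAA effect in *arf2-6* against that in the wild type, 1 point for each of the 1596 probe sets called in either genotype, with the 16 interaction calls in red and equality as a dashed line. The points follow the line (r = 0.943), and *IAA20* stands apart at a fitted 0.01 in wild type, with WT_control at the lowest value, and 1.49 in *arf2-6*.

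Without IAA, *AT2G43590*, of the chitinase family, was 2.39-fold higher in *arf2-6* (8.20 ± 0.08 against 9.46 ± 0.24 log2, SE of the difference 0.13, adjusted p = 0.0030). *AT5G62140* (2.44-fold), *AT5G62130* (2.14-fold) and *AT5G62200* (1.84-fold), which lie near the mutated locus, were also higher, at adjusted p of 0.0089, 8.3e-04 and 0.0053. *AT5G35940*, a jacalin-like lectin gene, was 3.14-fold lower in the mutant (log2 -1.65, SE 0.15, adjusted p = 8.3e-04), and *EULS3*, another lectin gene, was 1.83-fold lower (adjusted p = 0.0053). The other 14 of the 20 largest changes were called over all arrays, among them *AT2G47780* (log2 1.11), *AT1G67910* (0.93), *AT1G66800* (-1.47), the MATE efflux gene *AT5G38030* (-1.21), *GSTU26* (-0.94) and the wall acetylation relative *TBL41* (-0.85), but each of these 14 lost its call without 2 to 9 of the single arrays. The fit on the 6 control arrays alone called 2 probe sets, 1 of the 122 among them (*AT2G47780*, adjusted p = 0.0089), and the 6 genes named first stood at 0.11 to 0.15 there.

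No list was called between the genotypes in controls (lowest camera adjusted p = 0.50). Over all genes 0 list members passed, and 1 Aux/IAA gene was higher adjusted over the list alone. The root hair expansin *EXPA18* measured -0.90 log2 (adjusted p = 0.12), *IAA18* 0.47 (0.17), *LBD16* -0.23 and *COR47*, a dehydrin gene, -0.32. *PEX4*, the reference gene with the lowest p, measured -0.12, *LHCB4.1* 0.10 and *GH3.17* -0.35.

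In controls 122 probe sets were called, 50 higher and 72 lower in *arf2-6*. The count was 30, 44 and 456 without WT_control 1, 2 and 3, 26, 517 and 24 without arf2-6_control 1, 2 and 3, 72 without WT_IAA 1, and 79 and 61 without arf2-6_IAA 2 and 3. The balance turned to 244 higher and 212 lower without WT_control 3 and to 274 and 243 without arf2-6_control 2. WT_control 3 and arf2-6_control 2 deviated from their groups in the same way (r = 0.633 across probe sets), and without both, a choice made after seeing the data, the count was 713, 379 higher and 334 lower, with 20 of the 20 largest named changes still called. The mean 3' minus 5' difference over 6 pairs of control probe sets, a sign of RNA length, was 0.668 log2 in arf2-6_control 2 and 0.588 in WT_control 3, against 0.407 to 0.616 on the other arrays.

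With IAA, 3 of 5 tested lateral root and patterning regulators were lower in *arf2-6* than in the wild type. *PUCHI* stood at 5.79 ± 0.12 against 6.66 ± 0.13 log2 (difference -0.87, SE 0.08, adjusted p = 3.3e-04), *LBD16* at 7.27 ± 0.17 against 7.91 ± 0.14 (-0.64, SE 0.11, adjusted p = 0.0075), and *LBD29* differed by -0.62 log2 (SE 0.16, adjusted p = 0.035). The call of *LBD29* ended without WT_IAA 1 (adjusted p = 0.10), WT_IAA 2 (0.11), arf2-6_IAA 1 (0.10) or arf2-6_IAA 3 (0.088). *HAT2* (-0.33, adjusted p = 0.17) and *SHI* (0.08, adjusted p = 0.68) were not called over all genes. Adjusted over the list alone 4 were lower (camera adjusted p = 0.0025), and the call was lost at adjusted p = 0.087 with an estimated correlation. *IAA20*, at the lowest value on 2 of 3 WT_IAA arrays, was at least 2.94-fold higher (log2 1.56, SE 0.14, adjusted p = 4.3e-04). It was 1 of 4 Aux/IAA genes both ways of counting (camera adjusted p = 0.063).

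The largest falls held *AT1G14960* (4.72-fold lower, log2 -2.24, SE 0.32, adjusted p = 0.0032), *AT5G23840* (-1.79), *AT1G66800* (-1.78), the MATE efflux gene *AT5G38030* (-1.78), the nitrate transporter relative *AT3G45710* (-1.50) and *AT3G22570* (-1.49). The root hair expansins *EXPA18* (log2 -1.54, SE 0.25, adjusted p = 0.0055) and *EXPA7* (-0.96, SE 0.21, adjusted p = 0.018) were both lower. *EXPA7* reached adjusted p = 0.078 without WT_IAA 2, 0.073 without arf2-6_IAA 1 and 0.053 without arf2-6_IAA 3. *AT1G34510*, a class III peroxidase gene, was at least 3.28-fold lower, with adjusted p = 0.012 and 0.051 without arf2-6_IAA 3. Higher in the mutant were *AT2G47780* (log2 1.36, SE 0.16, adjusted p = 0.0013) and *AT1G67910* (1.17), and also the chloroplast-encoded *petG*, *psbB*, *psaC*, *ndhD* and *psbH* at 1.08 to 1.79 log2. Those 5 calls each ended without 1 to 8 of the single arrays, *psbB* only without arf2-6_IAA 3 (adjusted p = 0.071). The nuclear leaf photosynthesis markers were not called (camera adjusted p = 0.57, *LHCB4.1* 0.19 log2), nor were the GH3 genes (0.81), the expansins and XTHs (0.81) and the reference genes (0.52). *AT4G34270*, the reference gene with the lowest p, measured -0.34 log2 (adjusted p = 0.065), and 1 reference gene was lower adjusted over the list alone.

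The genotypes differed in 1249 probe sets with IAA, 416 higher and 833 lower in *arf2-6*, and in 2162 without the 2 control arrays named above. The count was 342 without WT_IAA 2, 490 without arf2-6_IAA 1, 796 without arf2-6_IAA 2 and 369 without arf2-6_IAA 3. The mean 3' minus 5' difference was 0.507 to 0.616 log2 on the WT_IAA arrays and 0.423 to 0.489 on the arf2-6_IAA arrays. Of the 122 control calls, 86 were called in the same direction with IAA, where independent lists would share 1.46 higher and 4.22 lower, and 1170 of the 1249 had the same sign in controls, with a median of 0.34 log2 there along that sign and of 0.60 with IAA. The group means of the 2 comparisons come from different arrays. Their error was estimated from all arrays together, so the 2 lists are not independent. The overlap expected for independent lists is therefore only a rough guide. Fitted on the control arrays alone, with fewer degrees of freedom, the control comparison kept 1 of the 122 calls.

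Averaged over treatments, root hair expansins were lower and a run of genes beside the mutated locus was higher in *arf2-6*. *EXPA18* (log2 -1.22, SE 0.18, adjusted p = 0.0019) and *EXPA7* (-0.81, SE 0.15, adjusted p = 0.0048), the 2 tested members of the root and root hair list, were lower on all 6 *arf2-6* arrays than on any of the 6 wild-type arrays. The 3 leaf photosynthesis markers were not called (*LHCB4.1* 0.15, *LHCB4.2* 0.07, *RCA* 0.02 log2, camera adjusted p = 0.56). Chloroplast-encoded genes among the 10 largest rises were *petG*, a cytochrome b6f subunit gene (3.25-fold, SE 0.34 log2, adjusted p = 0.0076), *psaC*, of photosystem I (2.19-fold), *rps16* (1.94-fold), *ndhA* (1.89-fold) and *rps2* (1.85-fold). The call of *rps2* (adjusted p = 0.024) ended without WT_control 1 (0.060), WT_IAA 1 (0.053), arf2-6_IAA 1 (0.056) or arf2-6_IAA 3 (0.062). *AT2G47780* (2.36-fold), *AT2G43590* (2.18-fold) and *AT1G67910* (2.07-fold) were higher as well.

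The largest averaged falls were *AT1G66800* (3.09-fold, log2 -1.63, SE 0.18, adjusted p = 6.1e-04), the peroxidase genes *AT1G34510* (-1.61, with arf2-6_IAA at the lowest value) and *AT5G19890* (-1.19), *AT5G23840* (-1.54), *AT5G47980* (-1.54), *AT5G35940* (-1.51, adjusted p = 5.9e-05), *AT5G38030* (-1.50) and *AT3G45710* (-1.30). *STZ* (-1.35, SE 0.31, adjusted p = 0.015) and *COR47* (-0.37, SE 0.08, adjusted p = 0.010), the 2 tested members of the touch, cold and handling list, were lower too. *IAA20* (0.82) and *IAA18* (0.36) were 2 of 4 Aux/IAA genes higher, over all genes and adjusted over the list alone (camera adjusted p = 0.12). *IAA18* (adjusted p = 0.042) lost its call without any 1 of 8 arrays, with adjusted p from 0.062 to 0.11, and *RR16* (0.26, adjusted p = 0.018) lost it without WT_IAA 2 (0.051). Of 5 lateral root and patterning regulators, *PUCHI* (-0.43) and *LBD16* (-0.43) were the 2 lower over all genes. They were 2 of the 4 lower adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.16 with an estimated correlation). The reference genes (0.43), the GH3 genes (0.68) and the expansins and XTHs (0.68, median 0.08 and mean -0.01 log2) were not called.

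Of the 18 tested genes within 25 genes of *AT5G62000* in gene order, 10 were higher in *arf2-6* and 0 lower, where the share called higher elsewhere would give 1.16. These genes, picked after their values were seen, were *PRH75*, an RNA helicase gene (log2 1.21, SE 0.20, adjusted p = 0.0033), *AT5G62140* (1.00), *AT5G62030* (0.82), *AT5G62130* (0.78), *AT5G62200* (0.76), *AT5G62150* (0.72), *TRM25* (0.67), *IQD23* (0.57), *AT5G61990* (0.41) and *CXE20* (0.38). On one side 9 of 11 tested genes were higher (median 0.72 log2), on the other 1 of 7 (median 0.03).

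**Figure D3:**
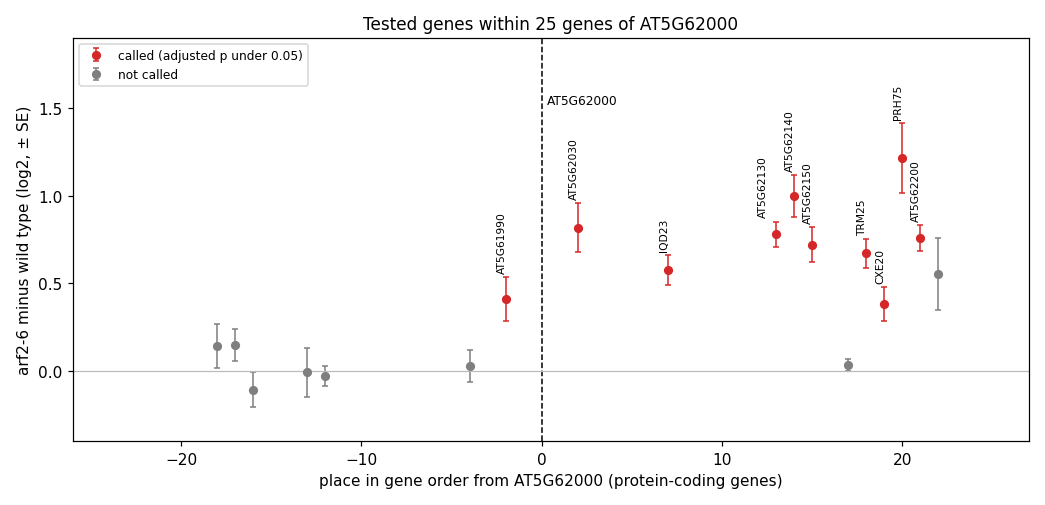
Averaged difference of *arf2-6* minus wild type (log2, ± SE) for the 18 tested genes within 25 genes of *AT5G62000*, by place in gene order, with calls in red. The 10 called genes lie at 0.38 to 1.21, 9 of them on one side.

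**Figure D4:**
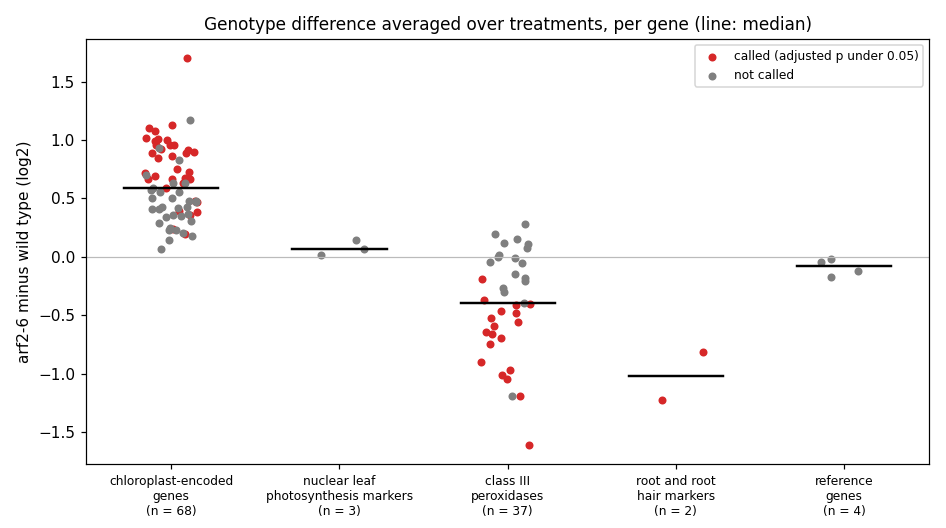
Averaged difference of *arf2-6* minus wild type (log2), 1 point per gene and a line at the median, for 3 lists fixed in advance and for chloroplast-encoded genes and class III peroxidases, which were listed only after the named genes were seen. Medians are 0.59 for the 68 chloroplast-encoded genes and -0.39 for the 37 peroxidases.

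The averaged genotype effect comprised 2256 calls, 1017 higher and 1239 lower, and 3558, 1911 higher and 1647 lower, without WT_control 3 and arf2-6_control 2. The balance also turned with array weights (2039 higher and 1946 lower) and without arf2-6_control 2 (1562 and 1539) or WT_control 3 (1320 and 1293). The count was 1409 without WT_IAA 2 and 1467 without arf2-6_IAA 3.

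The IAA response itself was called different for 16 probe sets. *IAA20* rose in *arf2-6* by 1.48 log2 more than in the wild type (SE 0.20, adjusted p = 0.028). *PUCHI* rose at least 2.02-fold in the wild type, and its response in the mutant was smaller by 0.87 log2 (interaction -0.87, SE 0.11, adjusted p = 0.023). Smaller responses in *arf2-6* were also called for *AT3G61930* (-1.13, adjusted p = 0.024), the class III peroxidase gene *AT5G14130* (-1.05, 0.028), *AT5G67430* (-0.86, 0.028) and *UGT76D1*, a glycosyltransferase gene (-0.78, 0.043). The list of lateral root and patterning regulators was lower in the interaction (mean -0.39 log2, camera adjusted p = 5.2e-04). It had 1 of 5 members lower over all genes, 3 adjusted over the list alone, and adjusted p = 0.051 with an estimated correlation. The Aux/IAA list was higher (mean 0.35, camera adjusted p = 0.049) through *IAA20* alone, 1 of 4 both ways of counting, and adjusted p = 0.30 with an estimated correlation. The GH3 genes (0.23), the expansins and XTHs (0.73), the leaf markers (0.73) and the reference genes (0.73) were not called.

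Of these 16 interaction calls in limma, 2 were higher and 14 lower. Of all 14215 probe sets, 520 had an unadjusted p under 0.05, below the share that tests without any difference would give. On all 6 control arrays 12 of the 16 lay at the lowest value. The count was 3, 2 and 6 without WT_control 1, 2 and 3, 3, 3 and 2 without arf2-6_control 1, 2 and 3, 5 and 45 without WT_IAA 2 and 3, 3 and 7 without arf2-6_IAA 1 and 3, and 3 without both WT_control 3 and arf2-6_control 2. None of the 6 named genes was called under every left-out array.

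Several lists gave no test. Of other ARF genes, auxin perception, ethylene biosynthesis, gibberellin and brassinosteroid metabolism, and jasmonate and wounding, 0 members had a named probe set that was tested, and they are not analysed here. Of the lists with 1 or 2 tested members, auxin transport (*WAG2*), auxin metabolism (*YUC6*), cell cycle (*AUR1*), clock (*GI*) and senescence (*WRKY6*) gave no called genotype difference in any of the 3 genotype comparisons. *YUC6* lay at the lowest value on all WT_IAA and arf2-6_IAA arrays and *WAG2* on all control arrays, where no genotype difference can be seen. *WRKY53* and *PDF1.2*, the tested defence genes, gave no call in any of the 6 comparisons. Both lay at the lowest value on all arrays of WT_control, arf2-6_control and arf2-6_IAA, where a difference cannot be seen. *EIN3*, the other tested ethylene signalling gene, measured 0.15 log2 with IAA in the wild type.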

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

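Of the tests in this part, those of swapped labels, RNA length, admixed wild-type RNA, other windows of genes, the local effect and the lowest deposited value were chosen only after the results were seen, as was every fit without WT_control 3 and arf2-6_control 2.

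The IAA response differed between the genotypes, by the interaction test in limma, for 16 probe sets. *IAA20* (interaction 1.48 log2) and 260376_at (1.47, adjusted p = 8.0e-05) responded more in *arf2-6*. The other 14 rose in the wild type and responded less in *arf2-6*. They were *AT3G61930* (-1.13), the class III peroxidase gene *AT5G14130* (-1.05), *PUCHI* (-0.87), *AT5G67430* (-0.86), *UGT76D1* (-0.78), *AT5G51380* (-0.72), *AT3G57950* (-0.60, adjusted p = 0.0048), *AT1G19230* (-0.47) and *AT4G15700* (-0.36). With them went 5 probe sets not listed with a gene, 246000_at (-0.88), 248548_at (-0.84), 251423_at (-0.82), 245075_at (-0.69) and 257583_at (-0.60). Apart from the 2 whose adjusted p is given, the 16 lay at 0.023 to 0.048. Of the 16, all were called between the genotypes in IAA-treated seedlings and 6 were called for IAA in both genotypes. As lists, the Aux/IAA genes had an interaction mean of 0.35 log2 and the lateral root and patterning regulators one of -0.39. Neither call held with an estimated correlation (adjusted p = 0.30 and 0.051).

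Part of these differences may rest on the lowest deposited value, since 75% of the 16 lay there on all 6 control arrays, where a difference between the genotypes before treatment cannot be seen. It may hide part of one in the 4 others too, since 3 of them lay there on 5 of 6 control arrays and *IAA20* on 4, all 3 wild-type controls among them. The fit without WT_control 3 and arf2-6_control 2 decides nothing about these arrays, since values at the lowest level cannot move (median size of the 16 interactions 98.5% of that with both arrays), and 260376_at alone stayed called (adjusted p = 0.0032, the others at 0.051 to 0.22), with fewer arrays behind the error. For the count, 1 of 100 drawn splits of genotype within treatment, the real one with 16 calls, reached it and the highest other gave 0. The averaged genotype effect was removed before these splits. For 12 of the 16 all 6 control arrays held the same value. There the removal set a genotype gap, which other splits turn into spread. The splits therefore do not decide on chance spread between these arrays. As the replicates may be technical, they do not test chance differences between cultures either. A change of the auxin response in *arf2-6* stays open as a hypothesis. So do control levels hidden at the lowest value, a part played by WT_control 3 and arf2-6_control 2, and chance spread.

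WT_control 3 and arf2-6_control 2 departed from their groups in the same way, with r = 0.633 across probe sets where the next highest pair of arrays of different groups reached 0.488. Both lay at least 2-fold from the other controls of their group, in the same direction, for 100 probe sets, 99 of them lower (*AT5G24690* at -1.78 and -3.03 log2), and they received low array weights of 0.331 and 0.293.

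Array-wide scaling was argued against, since r was 0.636 after quantile normalization, and IAA in the control cultures too, since the slopes of the 2 deviations on the IAA effect of the other genotype were -0.0209 and -0.0505. Swapped genotype labels would need both arrays nearer the other genotype, but WT_control 3 lay at 0.917 on a scale from the other genotype at 0 to the own at 1. Loss of longer transcripts was argued against as a shared cause by a Spearman rho of deviation on gene length of 0.00943 in WT_control 3, against -0.306 in arf2-6_control 2, so that such a loss stays open for the latter alone. Wild-type RNA in arf2-6_control 2, which lay at 0.502 on that scale, stays open, since among probe sets at the lowest value on the other *arf2-6* arrays only 1 could show a share of 50% (247468_at, picked after its values were seen, which would then have lain 1.44 log2 above its measured 5.64). Shorter RNA stays open, since 1 other array, WT_IAA 3 (0.616 log2), had a 3' minus 5' difference above that of WT_control 3. No biological explanation was tested, because the labels give the 2 arrays nothing in common that the other control arrays lack.

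For the run of higher genes beside *AT5G62000*, scaling was argued against, since the median of the 18 genes was 0.48 log2 under quantile normalization and 0.47 with centring on the upper quartile, and without WT_control 3 and arf2-6_control 2 it was 0.56 with 10 of 17 higher. Chance clustering was argued against too, since 0 of 7335 windows elsewhere with as many tested genes held 10 rising calls and the most was 5. A local effect linked to the mutated locus is a candidate explanation that stays open. Without the 4 genes that the naming rule had shown first, 6 of the other 14 were higher. The median of these 14 lay 0.28 log2 above that of the 105 tested genes further along (permutation p = 8e-05), short of the size set for this test. The permutation shuffled genes, so its p does not measure the spread between samples. The 15 tested genes from 26 to 50 places away had a median of 0.00 with 1 higher. Whether such an effect would come from the mutation itself, from sequence of another background carried along with it or from a change of the arm in this line was not tested.

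In each simple comparison the 6 arrays allow 10 splits, too few for a share under 0.05, and in each 1 split, the real one, reached the real count. The real count and the highest other were 1194 and 5 for IAA in the wild type, 1210 and 1 for IAA in *arf2-6*, 122 and 55 for genotype in controls, and 1249 and 0 for genotype with IAA. The split with 55 calls set WT_control 1 and 3 with arf2-6_control 2 and so follows the 2 arrays above, without which the real count was 713. Chance spread between these arrays was argued against for the averaged genotype effect, where 1 of 100 drawn splits reached the 2256 calls and the highest other gave 62. It was also argued against for the shared IAA calls, where 1 of 100 reached 808 and the highest other gave 1. None of these splits tests chance differences between cultures.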

How the results depend on the processing

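Filtering on probe sets above the lowest value in a group, leaving out WT_control 3 and arf2-6_control 2, and a fixed term shared by these arrays were chosen only after the results were seen. Both other scalings kept all counts within 1.5 times and reversed no gene or list called in the main fit. The counts were 1204 and 1212 for IAA in the wild type and 128 and 123 for genotype in controls. With no filter the genotype counts were 30 in controls and 648 with IAA. With the 50% filter the interaction count in limma was 0, and that filter tested only 1 of the 16. There 254 of 11373 probe sets had an unadjusted p under 0.05, also below the share that tests without any difference would give. Without the variance trend the interaction count was 8. Array weights gave 1862 for IAA in *arf2-6*, 479 for genotype in controls, 3128 with IAA and 3985 averaged. A 2-fold minimum, stricter by construction, left 349 and 337 for IAA in the wild type and *arf2-6*, 238 shared, 29, 152 and 100 for genotype in controls, with IAA and averaged, and 4 for the interaction. Fits on only the 6 arrays of a contrast, with fewer degrees of freedom, gave 622 for IAA in the wild type and 2 for genotype in controls. The filter above the lowest value gave 193 for genotype in controls and 3 for the interaction, the fit without both arrays 713 in controls, 2162 with IAA, 3558 averaged and 3 for the interaction, and the fixed term 400 in controls and 2098 with IAA. Unless a reason is given, the cause was not tested.

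Leaving out 1 array at a time, the counts ranged from 867 to 1304 for IAA in the wild type, 769 (without arf2-6_IAA 3) to 1391 for IAA in *arf2-6*, 608 to 788 for the shared calls, 24 (arf2-6_control 3) to 517 (arf2-6_control 2) for genotype in controls, 342 (WT_IAA 2) to 1560 with IAA, 1409 (WT_IAA 2) to 3101 averaged, and 2 (WT_control 2 or arf2-6_control 3) to 45 (WT_IAA 3) for the interaction. Other arrays that moved a count over 1.5 times are named with their values beside each count in the results. Of 36 list tests, camera called 12, 11 to 14 without any 1 array, 8 with an estimated correlation, and fry called 15.

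Whether the replicate number pairs the samples is not settled. Of 18 same-numbered pairs of arrays, 7 had deviations correlated over 0.1 (-0.497 to 0.488), and 7 of 12 arrays correlated best with a same-numbered one. Between control and IAA arrays numbered 1, 2 and 3, r was -0.081, 0.315 and 0.488 in the wild type. In *arf2-6* it was 0.287, 0.033 and 0.298. A pairing within each genotype was not modelled. With the replicate block the counts were 235 for genotype in controls and 6 for the interaction, and the others stayed within 1.5 times. Of the 254 other results, single genes and lists, 249 and 248 kept their side of the threshold under the other scalings. Results called in the main fit also had to keep their direction. The number was 224 with no filter, 247 without trend, 241 with weights and 245 with the block. It was 242 without both arrays and 227 to 244 without any 1 array. Of the results called in the main fit 0 reversed, and the direction of the others was not compared. Signal limits these results at the lowest deposited value, where differences are lower bounds. Pseudocounts were not run, since the values are log2, and the level of *ARF2* could not be identified here.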

Other observations

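The lists of class III peroxidases and chloroplast-encoded genes were chosen only after the named genes had been seen, as were all tests on them, whereas the gene families and the comparison of the genotype with the IAA effect were not.

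Class III peroxidases, secreted enzymes that oxidise phenolics and other substrates in the cell wall, were lower in *arf2-6* as a group. Averaged over treatments, 19 of 37 tested genes were lower and 0 higher over all genes, and 22 were lower adjusted over the list alone (median -0.39 log2, camera adjusted p = 8.7e-11). Examples are *AT1G30870* (-1.04, SE 0.16, adjusted p = 0.0023), *AT4G26010* (-1.01, SE 0.14, adjusted p = 0.0014), *AT5G64120* (-0.97) and *AT4G30170* (-0.90), while *AT1G49570* measured -1.19 (adjusted p = 0.080) and *PRXR1* -0.04. Of the 32 genes not seen beforehand, 14 were lower (median -0.28, camera adjusted p = 1.4e-07, and adjusted p = 0.046 with an estimated correlation). The root hair expansins *EXPA18* (-1.22) and *EXPA7* (-0.81), the 2 tested members of the root and root hair list, were lower in the same averaged comparison. The median was -0.28 in controls and -0.42 with IAA, and the list was not called for IAA itself (camera adjusted p = 0.59 in the wild type and 0.64 in *arf2-6*). Camera called it in the interaction (median -0.17, adjusted p = 9.9e-04, with 1 of 37 lower, and 0.032 for the 32), but with an estimated correlation the adjusted p was 0.41 for both. With an estimated correlation the averaged adjusted p of all 37 was 0.046, and it was 0.064 and 0.079 under the 2 other scalings, 0.051 to 0.073 without any 1 array except WT_control 3, WT_IAA 2 and WT_IAA 3, and 0.0080 to 0.093 over all alternatives. The count of lower genes was 17 to 21 without any 1 array and 23 of 36 without WT_control 3 and arf2-6_control 2.

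Chloroplast-encoded genes, transcribed inside the organelle, were higher in *arf2-6*, and all 68 tested members had a positive averaged difference. The members vary together (estimated correlation 0.42), so these 68 signs do not count as independent. Over all genes 35 were higher and 0 lower, and 54 were higher adjusted over the list alone (median 0.59 log2, camera adjusted p = 6.3e-19, and adjusted p = 0.067 with an estimated correlation). Beyond the genes named for the comparison, *ccsA* (0.95, SE 0.24, adjusted p = 0.020), *rbcL*, the large subunit of Rubisco (1.08, SE 0.27, adjusted p = 0.022), *rpoC1*, a polymerase subunit (0.90), and *accD* (0.91) were higher. Of the 60 not seen beforehand, 27 were higher (median 0.53, camera adjusted p = 3.8e-16, and adjusted p = 0.067 with an estimated correlation). The median was 0.49 in controls, with 0 called over all genes or over the list, and 0.69 with IAA, with 13 called. The mean 3' minus 5' difference of the control probe sets was 0.558 log2 in WT_IAA and 0.459 in arf2-6_IAA, with no overlap between the 2 groups, and 0.504 and 0.544 in WT_control and arf2-6_control. Camera called the list in the interaction too (median 0.10, adjusted p = 9.9e-04, and adjusted p = 0.41 with an estimated correlation), with 0 of 68 members called. The count of 35 was 20 without WT_control 1, 23 without WT_IAA 1, 21 without arf2-6_control 3, 12 without arf2-6_IAA 3, 12 with no filter and 44 without WT_control 3 and arf2-6_control 2. The 11 tested members of the family of organelle-encoded genes without a locus code, which were *nad*, *cox*, *ccb* and *orfX* genes (median 0.06 log2, 0 called, camera adjusted p = 0.36) and the 3 nuclear photosynthesis markers (camera adjusted p = 0.56) were not called.

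Among the 24 families, 21 had at least 5 tested members. SWEET sugar transporters had 2 of 5 members lower with IAA in each genotype, *SWEET2* (log2 -0.80 in the wild type and -0.82 in *arf2-6*, SE 0.16 for each) and the vacuolar *SWEET17* (-0.67 and -0.96, SE 0.13 for each). The count stayed at 2 without any 1 array. The SWEET set was called in the wild type (camera adjusted p = 0.016, and adjusted p = 0.45 with an estimated correlation) and in *arf2-6* (0.038, and 0.52 with an estimated correlation). Trichome birefringence-like genes, a family of wall polysaccharide acetylation, were called too (0.024 and 0.038, and 0.45 and 0.52 with an estimated correlation), with 1 and 4 of 14 lower. Without arf2-6_control 2 these counts turned to 3 and 2, and without arf2-6_IAA 3 the count in *arf2-6* was 2. *TBL25* was lower in both (log2 -0.89 and -0.79). Tetraspanins were called in *arf2-6* (0.038, 1 of 7 lower), and UDP-glycosyltransferases in the interaction (0.012, 1 of 28 lower). The glycosyltransferase count was 0 under both other scalings and without any 1 array except WT_IAA 1. With an estimated correlation the adjusted p was 0.52 for tetraspanins and 0.65 for glycosyltransferases. The SWEET call in the wild type ended without WT_control 2 (0.068) or WT_IAA 3 (0.072), and that in *arf2-6* without WT_control 2 (0.054), arf2-6_control 2 (0.10), arf2-6_control 3 (0.16) or arf2-6_IAA 1 (0.19). The trichome birefringence-like calls ended without WT_control 2 (0.068), WT_IAA 1 (0.071) or WT_IAA 3 (0.056) in the wild type and without WT_control 2 (0.052), arf2-6_control 2 (0.10) or arf2-6_IAA 1 (0.071) in *arf2-6*. The tetraspanin call ended without any 1 of 6 arrays, WT_control 2, arf2-6_control 2 and 3 and arf2-6_IAA 1, 2 and 3 (0.052 to 0.19), and the glycosyltransferase call without WT_control 3 (0.61) or WT_IAA 2 (0.37). Other settings ended calls as well. With no filter the adjusted p was 0.11 and 0.43 for SWEET in the wild type and *arf2-6*, 0.14 for tetraspanins and 0.066 for glycosyltransferases, which stood at 0.23 with the 50% filter. Array weights gave 0.068 in the wild type and 0.077 in *arf2-6* for both SWEET and trichome birefringence-like genes, and 0.077 for tetraspanins. Without WT_control 3 and arf2-6_control 2, a choice made after seeing the data, both families stood at 0.099 in *arf2-6*, tetraspanins at 0.18 and glycosyltransferases at 0.34, and a fixed term shared by these arrays, also chosen after, ended 4 calls (0.050 to 0.097). Camera called no other family in any of the 6 comparisons. Fry, which does not set a family against other genes, also called beta-glucosidases for IAA in the wild type (adjusted p = 0.023) and in *arf2-6* (0.011), GH9 glycosyl hydrolases (0.037) and expansins (0.049) in the wild type, and cytochrome P450s (0.035), glutathione S-transferases (0.043) and bZIP factors (0.048) in *arf2-6*. For the averaged genotype effect it called defensin-like, expansin, GH9 and trichome birefringence-like genes (0.031 each) and serine carboxypeptidase-like and IQ-domain genes (0.033 each), and it did not call glycosyltransferases in the interaction (0.78).

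A hypothesis that loss of *ARF2*, a repressor of auxin-responsive genes, moves transcripts the way IAA does was tested, and no such shift was seen. Across the 2151 probe sets called for the averaged IAA effect, which are not independent replicates, the averaged genotype and IAA differences had r = 0.0626. Of 100 splits, 65 gave a value as large in size, within -0.290 to 0.290. A correlation inside that range could not have been told from the splits, so a weak resemblance is not excluded. The 971 rising and 1180 falling probe sets alike tended to lie lower in *arf2-6*, 63.4 and 62.0% of them, with medians of -0.10 and -0.09 log2. Of 643 probe sets called for both effects, 223 rose with IAA and were lower in *arf2-6* and 274 fell with IAA and were lower, where independent lists would give 84.6 and 103. Higher in *arf2-6* were 54 that rose and 92 that fell, where independent lists would give 69.5 and 84.4. Both effects were tested with the same error estimate, so these lists are not independent.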
